A study of Homo sapiens with 8 samples.

How the data were processed

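The series holds 8 samples of total RNA from the PC-9 lung adenocarcinoma cell line, an established human line, in 4 variants with and without gefitinib. Groups were taken from the labels' entries for resistance and treatment: sensitive with DMSO (n = 1), sensitive with gefitinib (n = 1), resistant with DMSO (n = 3) and resistant with gefitinib (n = 3). Per the labels' protocols, cells were given 1 µM gefitinib for 48 h, RNA was extracted on columns, and Cy3-labelled cRNA was hybridised to one-colour Agilent arrays. The labels do not explain the suffix na, nor how the resistant lines were derived.

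The deposited files are the scanner output of each array, per the file headers made with Agilent Feature Extraction 10.10.1.1, a version that the submitters' processing notes also name. The intensity used here is the deposited processed signal, per the file headers after background subtraction on a linear scale with no normalization between arrays. The median spot intensity and the local background intensity in the deposited files served for an alternative. A table of the whole series was not used here, because the names of its 8 columns match no sample's labels. All 8 arrays lay on 1 slide with 1 scan, so slide and scan are no batch; the arrays fill 2 rows of the slide, the first with PC9 na and PC9 GR1 and the second with PC9 GR3 and PC9 GR.

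Each array had 62976 spots, of which 58717 were no controls and represented 42405 probes. Spots with an outlier flag were left out (262 to 639 per array), log2 of the processed signal was taken, each array's 75th percentile over non-control spots was subtracted, and spots of a probe were averaged. The median SD between spots of a probe printed repeatedly lay between 0.0517 and 0.0669. Probes were tested when well above background on at least 2 arrays (29338 probes). Of 25863 probes with a RefSeq accession, 24910 were named through the RefSeq gene table of assembly GRCh38.p14; other probes kept the accession or probe name of the array design and are counted but not named. No coordinates are given, because the array design and the table use different genome builds. A gene was represented by its probe with the highest mean signal, which gave 24351 genes, 14942 of them with a symbol, and other probes of the genes chosen in advance were compared. A gene counts as well above background on an array when any of its probes does. A gene not well above background on any array of a group has only a bound there: the fold is given as "at least", the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal.

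Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes) with Benjamini-Hochberg adjustment at 0.05, two-sided. Gefitinib effects in both arms and their difference came from 1 fit to all 8 arrays with the cell line as a block, which pairs the arrays by the line named in their titles. The arrays of a line deviated together from their group means across genes, with r = 0.584, 0.633 and 0.549 in PC9 GR1, PC9 GR3 and PC9 GR. The fit has 2 residual degrees of freedom, all from the 3 resistant pairs, and the lone sensitive pair was assumed to vary like them. Resistant and sensitive lines were compared on the 4 DMSO arrays and on the 4 gefitinib arrays, 3 against 1. The 3 resistant lines were compared by an F test on 6 arrays with a term for treatment, and deviations are of a line from the mean of the others. In that test the DMSO and gefitinib arrays of a line stand for its replicates, with 2 residual degrees of freedom. No 2 arrays of a group were alike: the SD of their log2 difference was at least 0.354.

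Before the data were examined, 29 gene lists, a set of core genes and the rule for named genes were fixed. The rule took the 8 largest rises and falls per comparison among genes past the threshold, changed at least 2-fold and in one direction in every line, filled where needed with the largest changes at an unadjusted p under 0.01, which are said not to pass; up to 4 members of each described list by their test statistic; the core genes; and 4 rises and falls per resistant line. Genes of this rule are given where they add to the text. Lists were tested with camera, which compares a list with all other genes, with a preset correlation between genes of 0.01, and again with an estimated correlation. No list in any of the 5 comparisons passed with the estimated correlation, for which camera has 2 residual degrees of freedom. In simulated data for the gefitinib effect in the resistant lines, with 24351 genes, a list of replication genes shifted by 1 log2 unit gave an adjusted p of 5.03e-38 with the preset correlation and 0.133 with the estimated one, and 1 list that was not shifted was also called with the preset correlation. The simulated genes varied independently of each other, whereas the estimated correlation within the real replication list was 0.89. The simulation therefore cannot show whether the preset correlation is valid for these data.

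The tests were run on simulated data of 24351 genes with known changes. For the gefitinib effect in the resistant lines, with 200 changed genes 60% of those changed 4-fold and 0% of those changed 2-fold were called, and with 5000 changed genes 97.4% and 85.4%. For the sensitive line with 5000 changed genes these shares were 88.4% and 44.2%, for the difference of the effects 82.1% and 23.2%, and for resistant against sensitive lines without drug 85.4% and 30.0%. With 200 changed genes none was called in these 3 comparisons. The simulated genes varied independently of each other, with a variance that did not depend on signal. In the real data a prior variance that depends on intensity changed the count for the difference from 0 to 2240. The simulated shares may therefore not hold for these data.

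Alternatives were median centring, quantile normalization, normexp background correction (offset 50) with quantile normalization, no filter on dim probes, probes above background on all 8 arrays, floored signals, the mean of a gene's probes, an intensity-dependent prior, leaving out each resistant line, fits without the block, and for resistant against sensitive lines fits to all 8 arrays and the slide row as a block. The planned normexp used the mean spot signal, which the files used here do not carry, and the median spot signal took its place as an alternative chosen after the data were seen. Random gene lists, 10000 per test, were matched on mean signal in 50 bins. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.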

Results

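Gene expression was measured in 4 variants of PC-9, a human lung adenocarcinoma cell line known for its dependence on mutant EGFR. The labels describe 1 variant, PC9 na, as sensitive to gefitinib, an inhibitor of the EGFR tyrosine kinase, and 3 variants, PC9 GR1, PC9 GR3 and PC9 GR, as resistant to it. RNA of each variant was collected after 48 h with 1 µM gefitinib or with the solvent DMSO, and each of the 8 samples was hybridised to 1 one-colour array with 62976 spots. The sensitive arm therefore holds 1 pair of arrays and the resistant arm 3 pairs, which are numbered here as replicates 1 (GR1), 2 (GR3) and 3 (GR). Between 63.8% and 71.9% of the spots of an array were well above background, and no spot was saturated. The 75th percentile of the processed intensity was 2000 and 952 on the untreated and treated PC9 na arrays. It was 1628 and 1049 for PC9 GR1, 1757 and 1459 for PC9 GR3, and 1994 and 2062 for PC9 GR. Levels and changes below are on the log2 scale after each array was set to its own 75th percentile, errors of changes are limma standard errors, and the number of arrays limits their precision. The replicates are cell lines of one origin by name, so p-values measure the spread between these lines. The exception is the comparison of the resistant lines with each other. There the DMSO and gefitinib arrays of a line serve as its replicates, and the error is the spread of the drug response between lines. No p-value measures the spread between cultures of a line given the same treatment.

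The first comparison asked which genes responded to gefitinib in the sensitive line. VTCN1, which encodes an inhibitory ligand of the B7 family, rose by 7.20 ± 0.50 and the stress-induced gene NUPR1 by 5.78 ± 0.28. PIGR, the receptor that carries polymeric immunoglobulins across epithelia, rose by 6.62 ± 0.56. TMEM130 rose at least 108-fold, and the ion exchanger gene SLC9A9, the organic anion transporter gene SLCO2B1, SH2D3C and DOCK8 rose at least 52.4-fold, 49.7-fold, 48.3-fold and 48.0-fold from signals not well above background. DUSP6, a phosphatase of ERK, fell by 4.89 ± 0.40, and the cornified envelope genes SPRR1B (-4.54 ± 0.47) and SPRR2A (-4.18 ± 0.56) fell too. ACOX2, a peroxisomal oxidase, fell at least 48.6-fold, COL13A1 at least 18.9-fold, and 3 genes of the interleukin-1 family and its receptors, IL1R2, IL1A and IL1RL1, at least 31.1-fold, 12.2-fold and 7.75-fold to signals not well above background. The adjusted p-values of these genes lay between 0.0145 and 0.0230.

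All 25 measured genes of the G2/M and mitosis list and all 26 of the G1/S and replication list fell in the sensitive line, with medians of -2.10 and -2.01. Among them were the mitotic genes BUB1B (-2.46 ± 0.16), AURKA (-2.32 ± 0.15), TPX2 (-2.29 ± 0.16) and CCNA2 (-2.67 ± 0.19), and the replication genes GINS2 (-2.95 ± 0.28), TYMS (-2.45 ± 0.23), RRM2 (-3.19 ± 0.30) and E2F1 (-2.67 ± 0.27). The camera test of these lists gave adjusted p = 9.16e-19 and 3.97e-15, and adjusted p = 0.586 and 0.597 with an estimated correlation. Of 20 genes that report ERK activity, 12 fell and EPHA4 alone rose (2.46 ± 0.40), with a median of -1.70. SPRY4 fell by 3.13 ± 0.18 and ETV4 by 3.24 ± 0.30, and ETV5 fell at least 10.7-fold (camera adjusted p = 4.89e-08, and adjusted p = 0.586 with an estimated correlation). A second SPRY4 probe went the other way, from -3.91 to -3.24. Of 24 ribosome biogenesis genes 20 fell, among them BOP1 (-2.26 ± 0.19), ODC1 (-2.86 ± 0.35) and NOP16 (-1.84 ± 0.23), and of 20 glycolysis genes 8 fell, with ENO2, PGAM1 and ENO1 at -1.46, -1.28 and -1.40. ALDOC, a brain isoform of aldolase, rose by 1.53 ± 0.36. Camera gave adjusted p = 8.90e-12 and 0.000377 for these 2 lists, and adjusted p = 0.597 and 0.586 with an estimated correlation.

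Other lists rose in the sensitive line. Of 21 antigen presentation genes 16 rose and none fell, with HLA-DMB at 2.61 ± 0.23, HLA-F at 1.88 ± 0.17, HLA-B at 1.72 ± 0.18 and the immunoproteasome gene PSMB10 at 1.65 ± 0.17. Probes of the HLA genes can cross-hybridise between near-identical family members, so which HLA gene changed is uncertain. Of 26 interferon-stimulated genes 13 rose, such as IFIT2 (2.98 ± 0.24), IFI6 (2.61 ± 0.23) and STAT2 (1.95 ± 0.20), while USP18 and OAS3 fell by 1.19 ± 0.16 and 1.24 ± 0.18. Camera gave adjusted p = 4.82e-06 for antigen presentation and 0.00125 for interferon, and adjusted p = 0.590 and 0.597 with an estimated correlation. Of 15 blood cell marker genes 7 rose and LAPTM5 fell, with a median of 0.91 (camera adjusted p = 0.0510). Of 23 lysosome and autophagy genes 10 rose, among them GABARAPL1 (3.15 ± 0.17), WIPI1 (3.31 ± 0.27) and CTSB (1.61 ± 0.18), with camera adjusted p = 0.000777, and adjusted p = 0.597 with an estimated correlation. Of 16 cell cycle inhibitor genes 8 rose, led by CDKN2B (3.59 ± 0.29) and CDKN2A (2.02 ± 0.17), and CDKN2C and CDKN2D fell by 0.93 ± 0.19 and 1.32 ± 0.19. Its camera adjusted p was 0.0131, with adjusted p = 0.597 with an estimated correlation. Epithelial genes (10 of 25 rose, ELF3 by 2.53 ± 0.20 and MUC1 by 3.14 ± 0.25) and mesenchymal genes (10 of 21 rose, CDH2 by 2.57 ± 0.22 and COL5A1 by 3.26 ± 0.29) rose alike, with camera adjusted p = 0.00663 and 0.00754, and adjusted p = 0.590 and 0.586 with an estimated correlation. In the BCL2 family, the pro-apoptotic BH3-only genes BMF, HRK, BCL2L11 and BBC3 rose by 4.14 ± 0.60, 3.43 ± 0.23, 1.78 ± 0.21 and 1.53 ± 0.16, and no other of its 16 genes passed the threshold (camera adjusted p = 0.473). The other BCL2L11 probes stood at -0.73 and -1.63 without drug and at -0.21 and -0.95 with it, smaller steps in the same direction.

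In total, 5908 of 24351 genes passed limma's test at an adjusted p of 0.05 in the sensitive line, 3418 higher and 2490 lower. This test takes its error from the 3 resistant pairs, because 1 sensitive pair has no spread of its own, and assumes that the sensitive line varied as they did. The median change of all genes was 0.18, so a gene's change relative to the median gene is lower by that amount. When arrays were centred on their medians it was -0.09 and after quantile normalization 0.02, and the share of higher genes among the calls, 57.9%, became 38.9% and 48.2%. Without the block for the line, 1400 genes passed, and without PC9 GR (replicate 3) 2088 did.

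**Figure D1:**
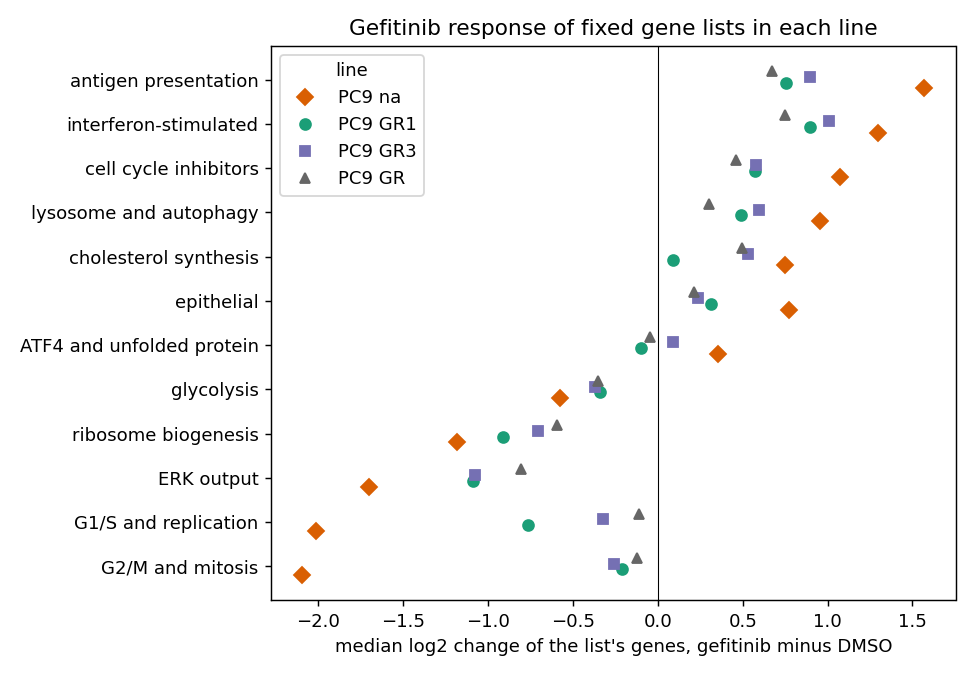
Median log2 change with gefitinib (treated minus DMSO, horizontal axis) of the measured genes of 12 lists fixed before the data were examined, with 1 symbol per cell line. The G2/M and G1/S lists stood at -2.10 and -2.01 in PC9 na and between -0.76 and -0.11 in the 3 resistant lines, while the interferon and antigen presentation lists were above 0 in all 4 lines.

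The second comparison asked which genes responded to gefitinib in the 3 resistant lines. VTCN1 rose by 6.93 ± 0.29 (n = 3 lines), NUPR1 by 3.85 ± 0.16, LBH by 3.71 ± 0.28, KANK4 by 4.14 ± 0.54 and the pro-apoptotic gene BMF by 3.63 ± 0.35. For VTCN1 1 and for KANK4 2 of the 3 untreated arrays were well above background. CCN5, the ubiquitin-like gene UBD and the basal keratin gene KRT14 rose at least 13.8-fold, 10.2-fold and 9.67-fold from signals not well above background. CEACAM6, a cell adhesion glycoprotein, fell by 4.40 ± 0.37, with 1 of the 3 treated arrays well above background. ACOX2 (-4.00 ± 0.14), DMBT1 (-3.74 ± 0.10), IL1B (-3.52 ± 0.39), IL1A (-3.22 ± 0.14) and IL1R2 (-3.22 ± 0.46) fell as well, where ACOX2, DMBT1 and IL1A were well above background on 2 and IL1R2 on 1 of the 3 treated arrays. COL13A1 and IL1RL1 fell at least 7.91-fold and 7.54-fold. The adjusted p-values of these 16 genes lay between 0.0172 and 0.0280, and each changed in one direction in all 3 lines.

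Of the 20 genes that report ERK activity, 15 fell in the resistant lines and EPHA4 rose (1.97 ± 0.23). DUSP6 fell by 3.01 ± 0.23, SPRY4 by 1.58 ± 0.10, ETV4 by 1.58 ± 0.18 and DUSP4 by 0.81 ± 0.09, and the list's median was -0.98 (camera adjusted p = 1.90e-08, and adjusted p = 0.545 with an estimated correlation). The second SPRY4 probe did not follow in any resistant line, and stood at -4.24, -4.18 and -4.00 in GR1, GR3 and GR without drug and at -4.09, -3.80 and -4.03 with it. Ligand genes of the EGFR family fell too: EPGN by 3.06 ± 0.33, AREG by 2.34 ± 0.29 and HBEGF by 1.94 ± 0.14, whereas that list as a whole did not pass (5 of 12 fell, 2 rose, camera adjusted p = 0.169). Of 24 ribosome biogenesis genes 21 fell, such as BOP1 (-1.01 ± 0.11), NOP16 (-1.12 ± 0.13) and ODC1 (-1.60 ± 0.20), and of 20 glycolysis genes 7 fell and ALDOC rose, with the falls led by HK2 (-2.51 ± 0.23), PDK1 (-0.98 ± 0.11) and LDHA (-0.58 ± 0.09). Camera gave adjusted p = 9.55e-12 and 5.95e-05 for these 2 lists, and adjusted p = 0.545 for both with an estimated correlation. Of the 26 interferon-stimulated genes 18 rose and none fell, among them BST2 (2.48 ± 0.21), IFIT1 (2.41 ± 0.23), MX2 (1.45 ± 0.11) and IFI44 (1.41 ± 0.10). Of 21 antigen presentation genes 15 rose, with HLA-DMA at 2.27 ± 0.22, HLA-DMB at 2.12 ± 0.13, HLA-F at 1.02 ± 0.10 and PSMB9 at 0.94 ± 0.09, and the peptide transporter gene TAP2 fell by 0.59 ± 0.11. Their camera adjusted p-values were 1.90e-08 and 3.21e-07, with adjusted p = 0.545 for both with an estimated correlation. Of the 15 blood cell marker genes 4 rose and CD68 fell, with a median of 0.48 (camera adjusted p = 0.0839).

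The proliferation lists behaved otherwise in the resistant lines. No gene of the 25 G2/M and mitosis genes passed the threshold, with TOP2A at -0.05 ± 0.09 and MKI67 at -0.36 ± 0.10, and 2 of the 26 G1/S genes fell, CCNE1 (-1.13 ± 0.11) and RRM2 (-0.81 ± 0.18). TOP2A changed sign when arrays were quantile normalized (0.051), and another MKI67 probe stood at -2.28, -2.11 and -2.00 in GR1, GR3 and GR without drug and at -2.42, -1.92 and -1.90 with it. The median of the mitosis list was -0.16. That of the replication list was -0.41 and differed between the lines, with -0.76 in PC9 GR1, where 25 of 26 genes were negative, -0.32 in PC9 GR3 and -0.11 in PC9 GR (percentiles 0, 0.79 and 31.8 of random lists matched on signal). Camera placed both below other genes (adjusted p = 0.000768 and 7.59e-05, and adjusted p = 0.595 and 0.636 with an estimated correlation). Camera does not match genes on signal. Against random lists matched on signal, the mitosis list lay at percentiles 8.1, 9.92 and 32.5 in GR1, GR3 and GR. Its median was thus within the range of such lists in each resistant line. Of 16 cell cycle inhibitor genes 10 rose, led by CDKN2B (2.31 ± 0.17, well above background on 1 of 3 untreated arrays), CCNG2 (1.35 ± 0.14) and PDCD4 (0.95 ± 0.11), with camera adjusted p = 0.000416, and adjusted p = 0.545 with an estimated correlation. The BH3-only genes BCL2L11, HRK and BBC3 rose by 1.05 ± 0.12, 1.00 ± 0.13 and 0.72 ± 0.09, while the BCL2 family list did not pass (4 of 16 rose, camera adjusted p = 0.731). The other BCL2L11 probes moved less, from -0.80, -0.64 and -0.60 to -0.48, -0.37 and -0.58 in GR1, GR3 and GR, and from -1.75, -1.70 and -1.92 to -1.13, -1.14 and -1.86. Mesenchymal genes (11 of 21 rose and 1 fell, with TGFB2 at 1.75 ± 0.13, ACTA2 at 1.64 ± 0.09 and COL5A1 at 2.22 ± 0.17) and epithelial genes (6 of 25 rose and 1 fell, with ELF3 at 2.23 ± 0.11 and MUC1 at 1.86 ± 0.14) rose together as before. Camera gave adjusted p = 0.0172 and 0.0376 for these lists, and adjusted p = 0.545 for both with an estimated correlation. EGFR itself stood at -0.65 ± 0.15 (adjusted p = 0.0545).

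In the resistant lines 4322 genes passed limma's test with the line as a block, 2574 higher and 1748 lower, and 766 genes changed at least 2-fold in one direction in all 3 lines. The share of higher genes among the calls was 59.6%, after median centring 38.7% and after quantile normalization 53.7%. Without the block 246 genes passed, without any filter on dim probes 0, and 0 when any 1 of the 3 lines was left out, which leaves 1 residual degree of freedom. In simulated data of that size, with 5000 changed genes among 24351, the test called 4320 genes with 2 resistant lines, and with 200 changed genes it called 0.

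The third comparison set the drug responses of the sensitive and resistant lines against each other. Of the 25 mitosis genes, all had a lower change in PC9 na than in the mean of the resistant lines, by a median of -1.84, and so did all 26 replication genes, by -1.69. With p-values adjusted over the list alone, 25 of 25 and 25 of 26 genes differed. BUB1B differed by -2.36 ± 0.19, TPX2 by -2.10 ± 0.18, TOP2A by -2.16 ± 0.19, GINS2 by -2.53 ± 0.32, TYMS by -2.23 ± 0.27 and E2F1 by -2.30 ± 0.31. Camera gave adjusted p = 4.17e-28 and 9.67e-20 for the lists, and adjusted p = 0.703 for both with an estimated correlation. The ERK list also differed, by a median of -0.90 (ETV5 by -2.25 ± 0.30, SPRY4 by -1.55 ± 0.21, 8 of 20 genes adjusted over the list alone), with camera adjusted p = 0.000296, and adjusted p = 0.703 with an estimated correlation. ETV5 was not well above background on the treated PC9 na array. Interferon-stimulated genes did not differ as a list (median 0.19, camera adjusted p = 0.778), although USP18 (-1.46 ± 0.18) and OAS3 (-1.47 ± 0.20) passed the test over the list alone in one direction and IFIT2 (1.74 ± 0.27), IFI6 and STAT2 in the other. The pro-apoptotic gene HRK differed by 2.43 ± 0.27 and the cytochrome gene CYP1A1 by 2.97 ± 0.41.

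Over all 24351 genes none passed limma's test of this difference, with 4751 at an unadjusted p under 0.05 and a smallest adjusted p of 0.102. The largest differences among genes with unadjusted p under 0.01 were PIGR (5.35 ± 0.65), DOCK8 (4.28 ± 0.77), DEPP1 (3.98 ± 0.56), TPPP (3.54 ± 0.61) and TMEM130 (3.50 ± 0.28) on one side. On the other were NPB (-3.32 ± 0.19), PCSK1N (-3.24 ± 0.26), CCDC78 (-3.23 ± 0.30), RAVER1 (-3.08 ± 0.31) and the histone gene H2BC6 (-3.00 ± 0.20). PIGR was not well above background on any resistant array, and DOCK8, TPPP and TMEM130 were not on any untreated array, so these 4 values are not measured differences. With a prior variance that depends on intensity 2240 genes passed, with normexp 2169 and with genes above background on all 8 arrays 1212. Of the calls in the 2 arms, which share no array, 1842 were higher in both, 1073 were lower in both and 16 were opposite. Both sets of calls use the error of the resistant pairs, so these counts have no independent expectation. Across genes, the changes of the 4 lines correlated with a mean Pearson r of 0.641 ± 0.0353 (SD, 6 pairs of lines). Genes are not independent replicates, so no p-value is given.

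**Figure D2:**
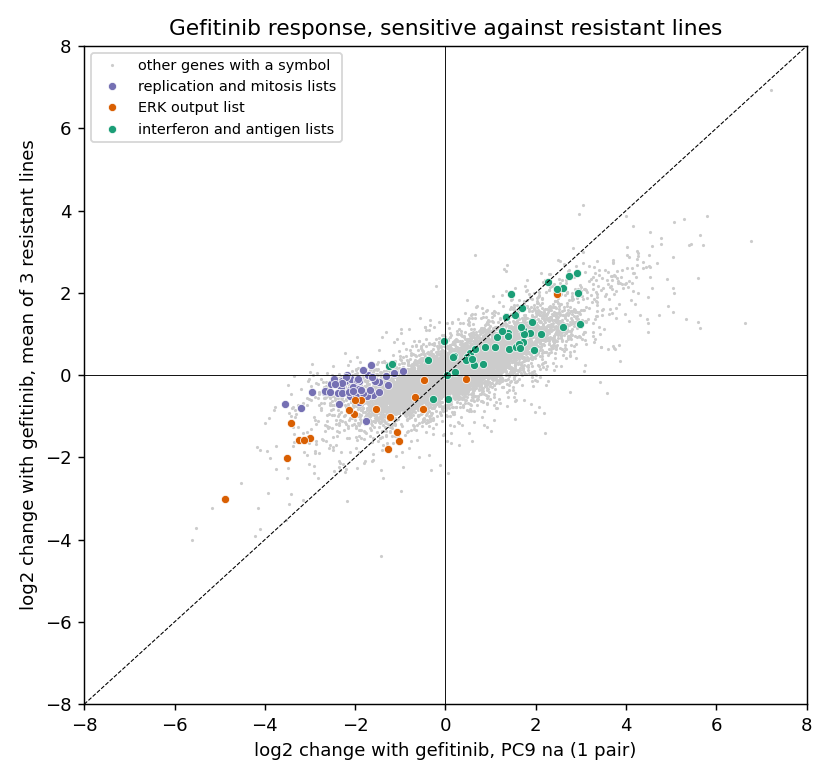
Each point is a gene with a symbol, at its log2 change with gefitinib in PC9 na (horizontal axis, 1 pair of arrays) and its mean log2 change in the 3 resistant lines (vertical axis); the dashed line marks equal change. The mitosis and replication genes lay to the left of the line, with list medians of -2.10 and -2.01 in PC9 na and -0.16 and -0.41 in the resistant lines.

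The fourth comparison asked how the resistant lines differed from the sensitive line without drug. All 16 measured squamous and basal epithelial genes had a lower mean in the resistant lines, with a median difference of -2.38. KRT13 differed by -5.36 ± 0.34, KRT17 by -2.56 ± 0.19 and SPRR3 by -3.69 ± 0.58 (n = 3 lines against 1), and KRT14 was at least 15.1-fold lower in the resistant lines, where it was not well above background. With p-values adjusted over the list alone 10 of the 16 genes differed, and camera gave adjusted p = 2.19e-08, and adjusted p = 0.524 with an estimated correlation. SPRR2 genes, such as SPRR2A given below, are near-identical copies, so which of the SPRR2 genes differed is uncertain. Of 21 ATF4 and unfolded protein response genes 20 were higher, by a median of 0.50, such as the asparagine synthetase gene ASNS (2.02 ± 0.49), VLDLR (0.86 ± 0.22) and SESN2 (0.86 ± 0.23), and with p-values adjusted over the list alone 0 of the 21 differed. Of 21 mesenchymal genes 15 were higher, by a median of 0.41, and CDH2 (2.33 ± 0.43), COL6A1 (1.49 ± 0.29) and SPARC passed over the list alone, while FN1 lay on the other side (-1.05 ± 0.28). Camera gave adjusted p = 1.66e-06 and 0.0179 for these 2 lists, and adjusted p = 0.524 for both with an estimated correlation. The adhesion gene PECAM1 (-2.70 ± 0.32) and MFAP5 (-3.26 ± 0.46), of the list of fibroblast and endothelial markers, were lower too; 3 of its 6 genes passed over the list alone (camera adjusted p = 0.000393, and adjusted p = 0.524 with an estimated correlation).

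FGFR1, a receptor of fibroblast growth factors, was higher by 1.54 ± 0.48 in the resistant lines without drug and its ligand gene FGF2 by 1.76 ± 0.62, each in all 3 lines (adjusted p = 0.447 and 0.473). FGFR1 stood at -2.21 in PC9 na and at -0.24, -1.32 and -0.44 in GR1, GR3 and GR. FGF2 stood at -3.42, -1.46, -2.51 and -1.01 in the same order, and a second FGF2 probe at -4.20, -2.24, -3.47 and -2.01. FGFR3 was lower (-1.06 ± 0.22), and the 15 genes of the FGF list did not move as a group (median -0.22, camera adjusted p = 0.946). With gefitinib FGFR1 fell by 1.98 ± 0.35 in PC9 na and changed by -0.62 ± 0.20 in the resistant lines (adjusted p = 0.104), with a difference of -1.37 ± 0.41 (adjusted p = 0.200). Of 20 genes of other receptor kinases that can bypass EGFR and their partners, 11 were higher and 9 lower without drug, with a median of 0.12, and the list did not pass (camera adjusted p = 0.163). MERTK, MET and AXL differed by 1.77 ± 0.34, 0.64 ± 0.24 and 0.57 ± 0.24 and PDGFA by -0.76 ± 0.24, none past the threshold (adjusted p = 0.268, 0.498, 0.516 and 0.451). EGFR differed by -0.17 ± 0.39 (0.076 without PC9 GR1) and VIM by 0.92 ± 0.86 (-0.17 with the slide row as a block).

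**Figure D3:**
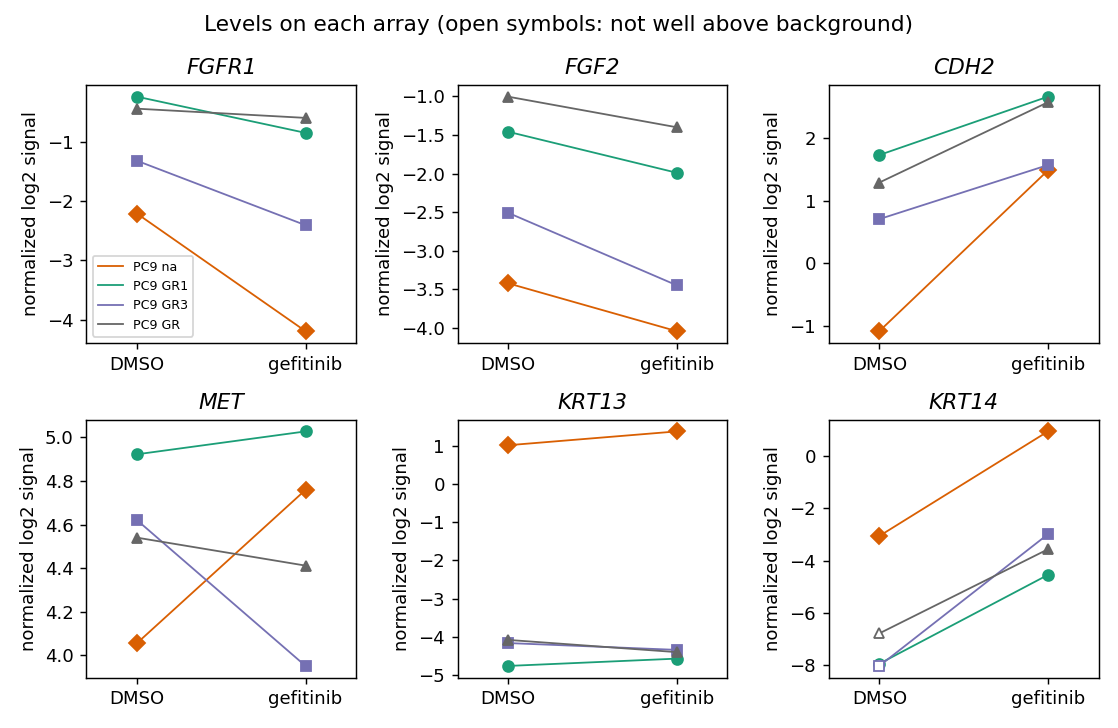
Normalized log2 signal of 6 genes (vertical axes) on the DMSO and the gefitinib array of each cell line, with 1 symbol and line per cell line and open symbols for signals not well above background. FGFR1, FGF2, CDH2 and MET were higher in the 3 resistant lines than in PC9 na with DMSO, and KRT13 and KRT14 were lower.

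No gene passed limma's test between the resistant and sensitive lines without drug, with 2439 at an unadjusted p under 0.05, a smallest adjusted p of 0.0607, and 601 genes that differed at least 2-fold in one direction in all 3 lines. The largest differences with unadjusted p under 0.01 were S100A8 (-6.20 ± 0.74), KRT13 as above, SPRR2A (-4.70 ± 0.92) and VCX2 (-4.36 ± 0.30, a gene with near-identical copies), and, beside KRT14, SLC1A3, BDKRB2 and SLC6A14, at least 31.5-fold, 20.7-fold and 8.69-fold lower in the resistant lines, where they were not well above background. In the other direction were MRC2 (2.82 ± 0.44) and ADTRP (2.66 ± 0.47), and SLC9A9, VXN and CABP7, at least 12.6-fold, 9.80-fold and 6.36-fold higher. With gefitinib on both sides no gene passed either (3855 at an unadjusted p under 0.05, smallest adjusted p 0.0916). There the resistant lines were higher in all 26 replication and all 25 mitosis genes, by medians of 1.91 and 1.92 (camera adjusted p = 8.58e-29 and 2.12e-29, and adjusted p = 0.655 for both with an estimated correlation), for example GINS2 by 3.06 ± 0.37. Squamous genes were again lower, by a median of -2.14 (camera adjusted p = 4.91e-08, and adjusted p = 0.655 with an estimated correlation). S100P (-6.16 ± 0.97) and KRT13 (-5.82 ± 0.29) were lower in the resistant lines, PIGR was at least 209-fold lower, and PCOLCE2 (4.04 ± 0.63) and MYB (3.02 ± 0.48) were higher. Other settings gave up to 349 genes without drug and up to 4540 with it, both with the error taken from within lines, and without PC9 GR1 (replicate 1) 190 genes passed with gefitinib.

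The fifth comparison set the 3 resistant lines against each other over both treatments. In PC9 GR3 the cancer-testis antigen genes PAGE2B and PAGE2, near-identical copies that one transcript may light up, and the transcription factor gene TCF4 were higher than in the other lines. PAGE2B stood at 2.10 and 2.01 with DMSO and gefitinib in PC9 GR3 and at -3.89 and -4.63 in PC9 GR, PAGE2 at 1.09 against -4.47 with DMSO, and TCF4 at -1.13 and -0.52 against -4.89 and -4.85 with DMSO and gefitinib. In PC9 GR1 none of these 3 genes was well above background. AGPAT4 was at least 35.8-fold higher in PC9 GR3, CHRDL1 and DCP1B were at least 84.6-fold and 35.1-fold lower there, and TUSC1 was lower by a log2 difference of -6.34 ± 0.12. In PC9 GR1 the phosphatase gene ACP5 was higher than the mean of the other lines by 3.74 ± 0.18 and RRAD by 3.28 ± 0.23. TUSC1 deviated there by 3.44 ± 0.12 from a mean that its low level in PC9 GR3 pulled down. SLITRK4 and PCSK5 were at least 20.6-fold and 17.1-fold lower in PC9 GR1 than the mean of the other lines. PAGE2B and PAGE2 were at least 40.1-fold and 23.5-fold lower than a mean that PC9 GR3 raised. These 2 bounds do not hold against PC9 GR alone. In PC9 GR, APBB1IP stood at 1.08 and 0.90 with DMSO and gefitinib. By any probe of the gene, 1 of the 4 arrays of the other lines was well above background (-7.85 for the probe that represents it). FAM133A and the cadherin gene CDH13 passed the F test but not the contrast of PC9 GR with the other lines (adjusted p = 0.0607 and 0.0833). Of the fixed lists, the squamous genes had the most members past the test, 6 of 16, with a median of -0.71 in PC9 GR1 and 0.65 in PC9 GR3, and FGF2 was lower in PC9 GR3 (-1.51 ± 0.15, adjusted p = 0.0435). In total 843 genes passed limma's F test, and the largest deviation was in PC9 GR3 for 467, in PC9 GR1 for 246 and in PC9 GR for 130. The contrasts of each line with the others had 1593, 376 and 36 genes past the threshold. Without PC9 GR1 39 genes passed and without PC9 GR3 or PC9 GR 0, and without a filter on dim probes 20 did.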

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

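Of the tests below, those of array signal, array centring and the single sensitive pair, of slide position and of other probes, and of dim interferon genes were chosen after the results were seen. The median changes with gefitinib of 11 lists differed between PC9 na and the mean of the resistant lines by the camera test with a preset correlation, and none did with an estimated correlation. The median differences were -1.84 for mitosis, -1.69 for replication, -0.90 for genes that report ERK activity, -0.63 for replication-dependent histones and -0.49 for ribosome biogenesis. They were 0.65 for NF-kB targets and cytokines, 0.48 for lysosome and autophagy, 0.47 for ATF4 and unfolded protein response, 0.45 for antigen presentation, 0.41 for blood cell markers and 0.40 for epithelial genes. The changes of KRT5 and CCDC78 had opposite signs in PC9 na and in all 3 resistant lines. The difference was -2.38 for KRT5, from -0.21 in PC9 na against 2.26, 2.44 and 1.83 in GR1, GR3 and GR. For CCDC78 it was -3.23, from -2.95 against 0.64, 0.13 and 0.07. Neither difference passed the test. The change of KRT5 in PC9 na and those of CCDC78 in GR3 and GR were small, so opposite responses are not shown. The groups of 1 and 3 arrays are too small to look for single outlying arrays.

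The replication and mitosis genes, 51 together, fell with gefitinib in PC9 na by a median of 1.76 log2 units more than in the resistant lines (a difference of -1.76). The lower signal of the treated PC9 na array is argued against as the cause, since 10000 random lists matched on signal gave medians from -0.11 to 0.18 and the percentile of the real median was 0. Centring of the arrays is argued against as well, because the median difference was at most -1.77 under 3 other normalizations. A general dampening of the drug response is argued against as the only cause by the kept share. These genes kept 14.7% of their change in the resistant lines, and random lists of other genes that fell as much kept 24.1% to 39.8% (percentile 0). Dampening may still account for part of the pattern, since the other genes went from a mean of -2.10 to -0.67, against -2.08 to -0.31. The random lists ignore the correlation within the lists (estimated at 0.89 for replication and 0.36 for mitosis), so their range is too narrow. In PC9 GR1 the replication list kept more, with a median of -0.76 against -2.01 in PC9 na. An accident of the 1 sensitive pair stays open, because the number of sensitive pairs is 1, and resistance of the lines, the biological difference in the design, may account for the pattern but cannot be told apart from such an accident.

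FGFR1 and FGF2 were higher in the 3 resistant lines than in PC9 na without drug, by differences that did not pass the threshold. A general rise of dim genes is argued against, because the lower of their percentiles among genes of like signal was 99.4. A single aberrant FGF2 probe is argued against by a second probe with a mean difference of 1.62, and for FGFR1 the number of other probes past the filter was 0, so a single aberrant FGFR1 probe stays open. Position on the slide cannot be told apart from the line either: within the slide row of PC9 na the smaller of the 2 differences was 1.96, but that row holds only PC9 GR1. Resistance may account for the pattern, and it was not tested apart from these.

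Interferon and antigen presentation genes, 47 together, had medians of 1.39 in PC9 na and 0.81, 0.91 and 0.67 in GR1, GR3 and GR with gefitinib. A general rise of dim genes is argued against, since the median lay at percentile 100 of matched random lists in each of the 4 lines. By the labels the RNA came from a lung adenocarcinoma cell line, so the design names no blood cells as a source. The marker values alone leave more RNA from blood cells open. The lists' median exceeded that of the markers PTPRC, LAPTM5 and CORO1A by at least 0.863 in each line. However, LAPTM5 and CORO1A stood at 0.04 and -1.50 in untreated PC9 na, levels that can hide a small share. The 15 blood cell markers together had medians of 0.91, 0.45, 0.65 and 0.18, at percentiles 99.8, 98.8, 99.8 and 94.3 of matched random lists, with CD3E, CD14, SPI1 and ITGB2 at 2.49, 2.23, 2.18 and 1.95 in PC9 na and LAPTM5 at -2.39. An effect of gefitinib on these genes may account for the pattern and stays open beside it.

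The 6 resistant arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. With the line as a block, the real split gave 4322 genes and the highest other split 0, and 1 of the 10 splits gave as many. In the other splits the drug effect of wrongly assigned arrays enters the error. A count of 0 there is largely built in and says little about chance. For lists the real split gave 15 and the highest other split 13, and again 1 of the 10 gave as many. The splits with 13 lists part only the PC9 GR pair. With the line as a block, a split that parts only 1 pair measures the gefitinib change of that line alone, up to its sign. Its count therefore holds a drug effect and does not show what chance gives. The other splits that also part all 3 pairs gave 5, 5 and 7 lists and differ in which line's treated array is exchanged with its DMSO array.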

How the results depend on the processing

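Among the alternatives, normexp on the median spot signal was chosen after seeing the data. The planned normexp on the mean spot signal was not run, since the files used here lack that signal. Median centring, quantile normalization and the mean of a gene's probes kept each count of genes within 1.5 times, and the 3 counts of 0 stayed at 0. Counts below are in the order resistant effect, sensitive effect, difference, resistant against sensitive without and with drug, and between resistant lines, where they moved by more. Normexp gave 6893 (resistant), 2169 (difference), 181 and 35 (without and with drug) and 5341 (between), with a mean r of 0.732. No filter on dim probes gave 0 (resistant) and 20 (between). Probes above background on all 8 arrays gave 6973, 1212, 171 and 121, and 4117, with a mean r of 0.761; fewer genes were tested. Floored signals gave 157 and 94 without and with drug and 1888 between lines. An intensity-dependent prior gave 8075, 2240, 142 and 167, and 6646. No block gave 246 (resistant) and 1400 (sensitive). For resistant against sensitive lines without and with drug, the line as a random block gave 113 and 356, error from within lines 349 and 4540, and the slide row as a block 275 with drug. Leaving out each resistant replicate gave 0 to 0 genes (resistant), 2088 to 4486 (sensitive), 0 to 190 (with drug), 0 to 39 (between) and 6 to 11 lists without drug, each with fewer samples. With an estimated correlation 0 lists passed in each of the 5 comparisons, against 15, 14, 11, 7 and 14.

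Changes of sign were TOP2A in the resistant lines (0.051 with quantile normalization, 0.058 with normexp), EGFR without drug (0.076 without replicate 1; -0.17 with all lines and as low as -0.37 without replicate 2) and VIM without drug (-0.17 with the slide row as a block). Of the results for named genes, 301 lost and 17 gained the threshold in the resistant lines and 32 and 6 in the sensitive line. For the difference 68 gained it, and for resistant against sensitive lines 67 without and 83 with drug. For lists none changed sign, and 5, 5, 4 and 7 results lost the threshold in the difference, the resistant effect and resistant against sensitive lines without and with drug. Except where construction is named, the cause was not tested. Signal over background limits dim genes, for which changes are bounds.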

Other observations

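Other lists moved with gefitinib too. Cholesterol genes rose in PC9 na (6 of 22, camera adjusted p = 0.0310, and adjusted p = 0.656 with an estimated correlation) and in the resistant lines (5 of 22, with TM7SF2 at 1.66, and 1 fell, camera adjusted p = 0.00872, and adjusted p = 0.595 with an estimated correlation). Genes of the NRF2 and xenobiotic list rose (5 and 6 of 21, while TIPARP fell in the resistant lines, adjusted p = 0.0329 and 0.0363, and adjusted p = 0.656 and 0.636 with an estimated correlation), and replication-dependent histone genes, near-identical copies, fell (5 and 4 of 11, while H1-2 rose in PC9 na, adjusted p = 0.0115 and 0.00504, and adjusted p = 0.656 and 0.595 with an estimated correlation). In the resistant lines 9 of 23 lysosome and autophagy genes rose and NPC1 fell (adjusted p = 0.000661, and adjusted p = 0.595 with an estimated correlation), and 5 of 13 heat shock genes fell while CRYAB rose (adjusted p = 0.0150, and adjusted p = 0.545 with an estimated correlation; in PC9 na 0.422). Against random lists matched on signal, the heat shock list lay at percentiles 0.24, 33.6 and 1.06 in GR1, GR3 and GR. The cholesterol list lay at 85.6, 100 and 100, and the histone list at 3.61, 0.02 and 0. Heat shock in GR3 and the other 2 lists in GR1 were thus within the range of such lists. TIPARP, H1-2, NPC1 and CRYAB were named after their values were seen. Among squamous genes KRT5 (2.18) and IVL (1.14) rose in the resistant lines and SPRR1B fell (-2.63), with no shift of the list (adjusted p = 0.850, and 0.763 in PC9 na). IGFBP3 rose by 3.48 in PC9 na and 2.13 in the resistant lines, and VEGFA fell by 1.98 in PC9 na (-1.76 in the resistant lines).

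The BCL2 family and squamous lists, given above, passed in neither arm. The other lists that did not pass in either arm had these camera adjusted p-values in PC9 na and in the resistant lines: blood cell markers 0.0510 and 0.0839, ATF4 and unfolded protein response 0.132 and 0.809, NF-kB targets 0.164 and 0.517, liver and intestine 0.251 and 0.0571, alveolar 0.293 and 0.515, EGFR family 0.409 and 0.169, neuroendocrine 0.422 and 0.262, bypass receptor kinases 0.647 and 0.662, ribosomal proteins 0.647 and 0.0520, FGF 0.728 and 0.337, stem cell and efflux 0.75 and 0.262, and fibroblast and endothelial markers 0.887 and 0.850. Without drug, the replication list was higher in the resistant lines (24 of 26 genes, median 0.27). The ribosomal protein list was higher too (22 of 22, median 0.23), and the alveolar list was lower (12 of 15, median -0.36). Camera gave adjusted p = 0.000128, 0.000185 and 0.0432, and adjusted p = 0.524, 0.600 and 0.524 with an estimated correlation. Camera does not match genes on signal. Among random lists matched on signal, these lists lay at percentiles 99.88, 98.49 and 1.61. The range of such lists reached 0.22 for the ribosomal protein list, close to its median. That range is too narrow, because it ignores the correlation within the list (estimated at 0.72). A rise particular to ribosomal protein genes is therefore not shown.

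The share of the PC9 na change that the resistant lines kept was computed for 18 lists, over members that changed at least 2-fold in PC9 na in the direction of the list's median there. It was 9.94% for mitosis, 19.2% for replication, 30.5% for ATF4 and unfolded protein response, 31.4% for replication-dependent histones, 38.9% for blood cell markers and 39.5% for NF-kB targets. It was 46.2% for lysosome and autophagy, 49.0% for cell cycle inhibitors, 52.1% for glycolysis, 54.9% for ribosome biogenesis, 55.9% for mesenchymal genes, 57.5% for bypass receptor kinases and 57.9% for genes that report ERK activity. It was 60.2% for epithelial genes, 65.9% for antigen presentation, 68.7% for cholesterol, 71.2% for interferon and 92.6% for the EGFR family. These shares describe the chosen members only. Over all members, the mean changes in PC9 na and in the resistant lines were 0.58 and 0.07 for ATF4 and unfolded protein response, 0.54 and -0.10 for NF-kB targets and 0.33 and 0.10 for bypass receptor kinases.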
